A study of Mus musculus with 6 samples.

How the data were processed

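Messenger RNA of 500 sorted 2D2+ CD4+ T cells per library was measured in 6 libraries, 3 from HDAC1-cKO and 3 from WT donor cells. Per the labels' protocols, polyadenylated RNA was turned into full-length cDNA by Smart-seq2, which amplifies RNA of few cells, libraries were made with a transposase kit that does not mark strand, and 50-base single reads were sequenced on an Illumina HiSeq instrument. The series text states that 2 mice were pooled for each biological replicate. It does not say whether replicates of both genotypes share donors or a day.

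The authors deposited whole-number read counts per gene, not normalized, in 1 table of 55536 genes and 6 columns. Per the submitters' processing notes, the tools used were Picard 2.19.2, STAR 2.5.2b, DESeq2 1.24.0 and R 3.6.1, and the builds named were GRCm38/mm10 and GRCh38/hg38. What each tool did, the read counter, the treatment of reads that map to several places and the strand setting are not given in the sources used here. The gene identifiers and coordinates in the deposited count table are those of GENCODE M21 on GRCm38. The authors also deposited FPKM values for the same genes and libraries; across 10866 genes with a count of at least 50 in each library, the ratio of FPKM to count was 1 constant per gene times 1 factor per library. That factor equalled the median-of-ratios size factor of DESeq2, not the total count, so the FPKM are comparable between libraries for a gene. Each column name matched the description of 1 sample, and 0 columns were left without a sample.

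Groups were taken from the genotype in the labels. Genes were kept by edgeR's filterByExpr, which left 15519 genes with at least 99.92% of the counts of every library. Counts were scaled by TMM and tested with edgeR's quasi-likelihood F test with robust estimation (edgeR 4.0.16 in R 4.3.3), two-sided, with genotype as the term, and a Benjamini-Hochberg adjusted p under 0.05 was required. CPM values were computed on the TMM-scaled total count of each library. Standard errors of log2 fold changes were derived from the fold change and its quasi-likelihood p. The smallest library held 19956153 and the largest 55900237 counts, and the reads carry no molecular identifiers, so that counts are not independent molecules. All pairs of libraries differed by more than sampling noise (chi-square per degree of freedom from 12.0 to 150.5), so no pair was a repeat deposit of the same library; that each is a biological replicate rests on the series text.

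In all, 32 gene lists were fixed before the data were examined, knowing that the study concerns T cell trafficking; of 708 distinct members 630 were tested. In the glycolysis list, Aldoa matched 2 gene identifiers, and both were kept. Lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, adjusted over 32 lists, and again with an estimated correlation and with fry. Each list is also described by its genes past the threshold over all genes tested and adjusted over the list alone. Genes to be named were also fixed in advance. They were Hdac1 and Hdac2; in each direction the 12 genes with the lowest p among those called whose libraries separate by genotype, leaving out predicted gene symbols and antibody or receptor segments; in each list up to 4 called members, or the lowest-p members up to 2 where fewer than 2 were called, given as values; and Ccr4, Ccr6 and Itga4. A few genes that the rule names are not reported here. Features outside this rule are said to have been chosen after their values were seen.

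The tests were tried on simulated counts for the same 15519 genes and library sizes, with 200 genes changed. These counts were drawn independently for each gene from dispersions that edgeR had estimated, with no GC trend in any library. The rates may thus favour edgeR and need not hold for the real comparison. In the simulated HDAC1-cKO against WT comparison edgeR recovered 39.2% of genes changed 2-fold and 68.0% of those changed 4-fold, and 5.5% of its calls were false. DESeq2 1.42.0 recovered 53.0% and 73.0% with 25.9% false calls, and limma-voom with sample weights 32.0% and 67.0% with 3.0% false calls.

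Alternatives fixed before the data were examined were other scaling factors, no or a stricter low-count filter (at least 10 CPM in 3 libraries), DESeq2, limma-voom with sample weights, edgeR without robust estimation, limma on log2(FPKM + 1), counts thinned to the smallest total, a replicate block, other thresholds and leaving out each library. Offsets that remove each library's trend with GC content, or with GC content and transcript length, were added after seeing the data. GC content and shared 50-base stretches were taken from the GENCODE M21 transcripts, and exon overlaps from its annotation. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.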

Results

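Gene expression was measured by low-input RNA sequencing in CD4+ T cells that carried the 2D2 transgene, a T cell receptor specific for a peptide of myelin oligodendrocyte glycoprotein (MOG). The cells lacked the histone deacetylase HDAC1 through Cre recombinase under the Cd4 promoter (HDAC1-cKO) or carried the same floxed alleles without Cre (WT). Naive donor cells were injected into recipient mice distinguishable by their CD45 allele, and 18 hours later the recipients received MOG peptide in complete Freund's adjuvant in the footpad. After 4 days, 500 donor-derived 2D2+ CD4+ cells were sorted from the draining popliteal lymph nodes for each library. Each library pooled 2 mice, and each genotype had 3 biological replicates. The total count was 32478107, 36307610 and 19956153 in HDAC1-cKO replicates 1, 2 and 3, and 52071923, 55900237 and 39036751 in WT replicates 1, 2 and 3, so that the WT libraries were the deeper ones. In every library, Trbv16 took 98.6 to 98.96% of the counts of T cell receptor beta variable segments.

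Hdac1 transcripts were far lower in all 3 HDAC1-cKO libraries than in WT. Hdac1 (ENSMUSG00000028800, chromosome 4, 129516104 to 129542713 on the minus strand, GRCm38) stood at 15.8 ± 1.32 CPM in HDAC1-cKO and 238 ± 5.06 CPM in WT (SD, n = 3 libraries per group), with values of 17.2, 14.7 and 15.4 CPM against 234, 236 and 244 CPM. It fell by 3.91 ± 0.12 on the log2 scale (SE, edgeR adjusted p = 9.59e-06), which left 6.63% of the WT level. In the deposited FPKM the corresponding levels were 7.63 ± 0.652 and 115.5 ± 2.90 (SD, n = 3). The count covers the whole gene, and the sources used here do not say which exons Cre removes. Reads from exons that Cre leaves may be part of these values, and the source of the remaining 6.63% was not tested. Hdac2, the closest relative of Hdac1 and its partner in the same corepressor complexes, stood at 86.6 ± 31.2 CPM in HDAC1-cKO and 78.4 ± 8.31 CPM in WT (SD, n = 3), a log2 difference of 0.14 ± 0.25 (SE, edgeR adjusted p = 0.840). This difference was 0.385 without HDAC1-cKO replicate 2 and -0.125 without HDAC1-cKO replicate 3 (edgeR adjusted p = 0.183 and 0.875).

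The comparison asked which genes differ between HDAC1-cKO and WT donor T cells 4 days after immunisation. The cells lacked HDAC1 before transfer, and no cells from before transfer or without immunisation were measured. Differences that were present before activation can therefore not be told apart from later ones. Of 15519 genes tested, 152 were higher and 154 lower in HDAC1-cKO (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Of the higher genes 145 were protein-coding, with a median log2 fold change of 1.38, and 103 changed by at least 2-fold. Of the lower genes 132 were protein-coding, with a median of -1.11, and 86 changed by at least 2-fold. In all 306 the 3 libraries of one genotype lay above the 3 of the other, which was also the case for 24.6% of all tested genes, against 10% by chance.

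**Figure D1:**
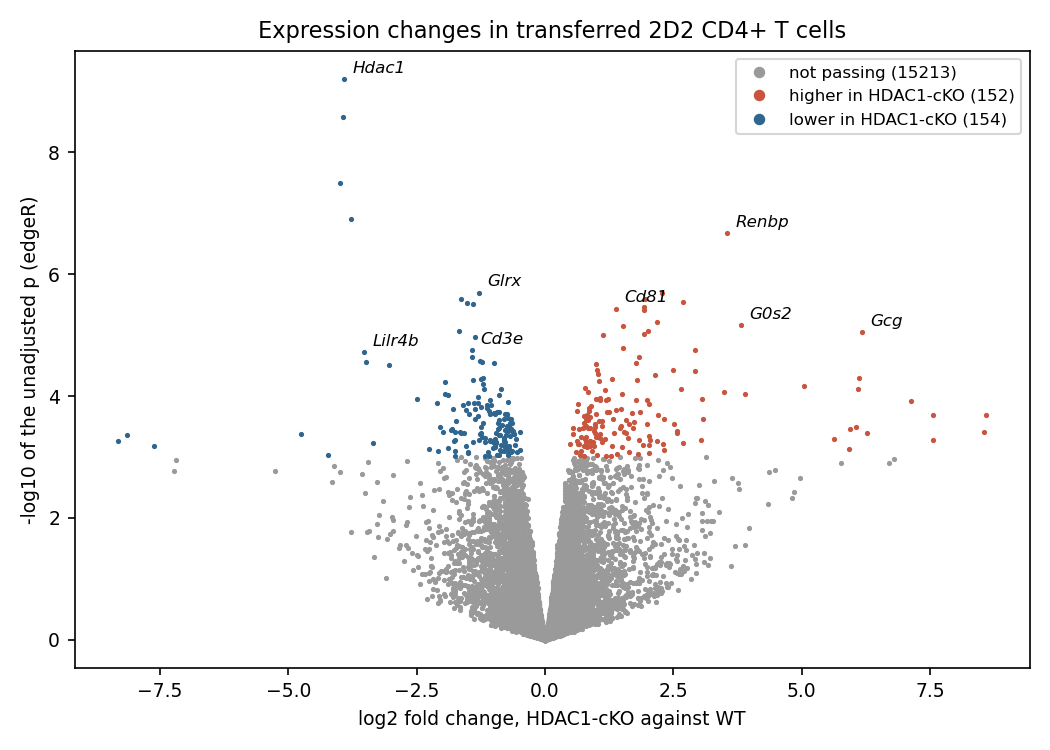
Each point is 1 of 15519 tested genes, with the log2 fold change of HDAC1-cKO against WT on the x axis and -log10 of the unadjusted edgeR p on the y axis. The 152 higher genes are red, the 154 lower genes blue and the rest grey; Hdac1 has the lowest p of all tested genes, with a log2 fold change of -3.91.

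Genes that rose without HDAC1 included several that WT cells hardly used. Renbp, which encodes an N-acetylglucosamine epimerase (chromosome X, 73922121 to 73930850), rose from 1.45 ± 0.120 CPM in WT to 16.9 ± 2.65 CPM in HDAC1-cKO (SD, n = 3), a log2 fold change of 3.54 ± 0.22 (SE, edgeR adjusted p = 0.000647). Gcg, the gene of proglucagon, rose from 0.105 ± 0.0737 to 7.40 ± 3.59 CPM (SD, n = 3; log2 fold change 6.17 ± 0.62, SE). G0s2, an inhibitor of triglyceride lipase, rose from 0.205 ± 0.0289 to 2.91 ± 0.287 CPM. Hmgn3, a nucleosome-binding protein, and Nt5dc2, a nucleotidase family member, rose by 2.28 ± 0.19 and 2.69 ± 0.24 on the log2 scale (SE). Among genes already expressed in WT, the tetraspanin gene Cd81 rose from 58.3 ± 4.61 to 150.9 ± 15.8 CPM (SD, n = 3). Plscr3 and Chchd10, which encode mitochondrial proteins, rose by 1.94 ± 0.17 and 1.53 ± 0.15 on the log2 scale (SE), and Inka1, Ift22 and Ddah2 by 1.93 ± 0.17, 1.93 ± 0.18 and 2.17 ± 0.21. The genes named so far in this paragraph had edgeR adjusted p values from 0.000647 to 0.00654. The calls of Chchd10 and Gcg ended without WT replicate 3 and without WT replicate 2, respectively (edgeR adjusted p = 0.0504 and 0.0520). Without strand, counts of Plscr3 can include reads of Tnk1, whose exons cover 28.3% of its exon bases on the other strand, and those of Chchd10 and Nt5dc2 can include reads of Mmp11 and Stab1, which overlap 9.8% and 4.7% of theirs and stood at 0.939 and 0.454 CPM in HDAC1-cKO.

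Survival factors, surface receptors and a glucocorticoid-activating enzyme were among the genes that fell. Ms4a4b, a membrane protein abundant in T cells, fell from 1354 ± 86.0 to 421 ± 95.3 CPM (SD, n = 3), and its neighbour on chromosome 19, Ms4a4c, from 134 ± 16.7 to 42.9 ± 4.58 CPM. Cd3e, the epsilon chain of the CD3 complex, fell from 117 ± 16.2 to 43.6 ± 6.61 CPM (log2 fold change -1.42 ± 0.16, SE, edgeR adjusted p = 0.0102). The glutaredoxin gene Glrx (chromosome 13, 75839868 to 75850154) fell from 290.7 ± 24.0 to 119.8 ± 5.66 CPM (log2 fold change -1.28 ± 0.11, SE, edgeR adjusted p = 0.00391). The antiapoptotic genes Bcl2a1a, Bcl2a1b and Bcl2a1d on chromosome 9 fell by 1.41 ± 0.16, 1.36 ± 0.14 and 1.40 ± 0.12 on the log2 scale (SE). Samd9l, an interferon-inducible antiviral gene, had a log2 fold change of -1.52 ± 0.13, the receptor gene Lilr4b one of -3.52 ± 0.39, and Hsd11b1, which regenerates active glucocorticoid, one of -1.27 ± 0.15. The processed pseudogene AC125456.1 (chromosome 18, 85847280 to 85848729), which shares 12.2% of its 50-base stretches with Hdac1 transcripts, fell with Hdac1 (log2 fold change -3.77 ± 0.22, SE). Bcl2a1a, Bcl2a1b and Bcl2a1d are near-identical copies, as are to a lesser degree Ms4a4b and Ms4a4c, so how their reads were split between copies is uncertain. The same holds for Lilr4b and its neighbour Lilrb4a. The Bcl2a1b call ended without HDAC1-cKO replicate 1 or 3, that of Lilr4b without HDAC1-cKO replicate 1 or WT replicate 3, and those of Cd3e and Hsd11b1 without HDAC1-cKO replicate 1 or 3 or WT replicate 3, with edgeR adjusted p up to 0.0674, 0.0606, 0.0716 and 0.0902. That of Bcl2a1a ended without any 1 library other than HDAC1-cKO replicate 2 (edgeR adjusted p up to 0.0716).

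**Figure D2:**
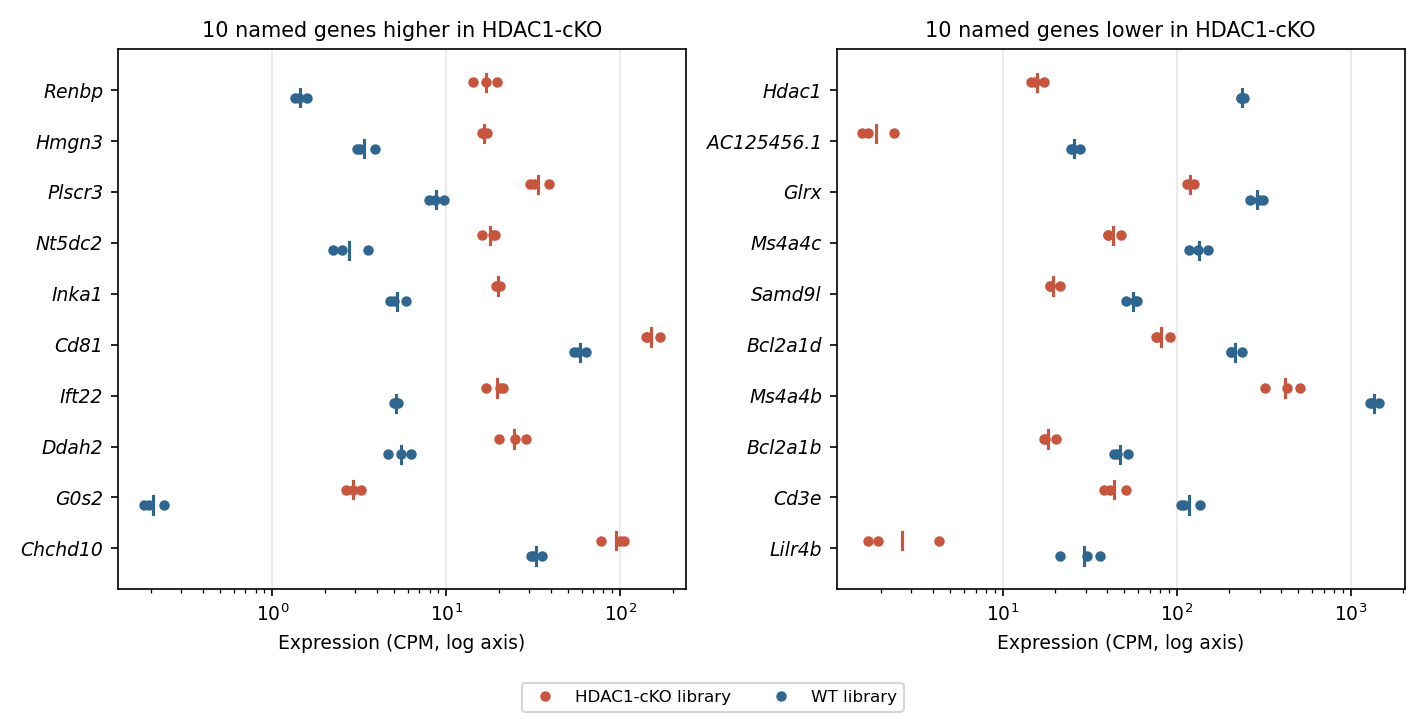
Expression of the 10 higher and 10 lower genes with the lowest p under the naming rule in each library, in CPM on a log axis, with 1 point per library (n = 3 per genotype, HDAC1-cKO red, WT blue) and a bar at each mean. The genotypes do not overlap for any gene drawn, because the naming rule requires it. Hdac1 stands at 14.7 to 17.2 CPM in HDAC1-cKO and at 234 to 244 CPM in WT.

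HDAC1-cKO replicate 2 stood apart from the other libraries. The first principal component, with 34.6% of the variance, separated the genotypes, and the second, with 21.8%, placed this library at -58.9 against -18.0 to 37.4 for the others. Across 6946 well-expressed genes, which are not independent replicates, its deviation from the mean of all libraries correlated with GC content at a Pearson r of 0.609, against -0.308 to -0.076 in the other 5. Mitochondrially encoded genes took 0.922% of its counts and 1.34 to 1.67% elsewhere. Without this library 258 genes were higher and 368 lower, with 280 of the 306 genes kept. Leaving out any other library lowered the numbers, to 15 higher and 14 lower without HDAC1-cKO replicate 1, 15 and 13 without HDAC1-cKO replicate 3, and 26 and 23, 18 and 18, and 16 and 10 without WT replicates 1, 2 and 3. Of the 38 genes under the naming rule that passed the threshold, 17 passed it without any 1 library. Across the same 6946 genes, the deviations also correlated with log transcript length, and here the libraries split by genotype. Pearson r was -0.027, -0.261 and -0.031 in HDAC1-cKO replicates 1, 2 and 3, and 0.065, 0.263 and 0.139 in WT replicates 1, 2 and 3. The source of this length trend was not tested. It could shift lists of mostly short or mostly long transcripts, and the transcript lengths of the lists were not compared. With GC and length offsets 10 lists were past the camera threshold with the preset correlation, against 7 without offsets.

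Trafficking genes fixed in advance as 3 lists leaned lower in HDAC1-cKO, with few single genes past the threshold. Among 15 tested chemokine receptors, 14 had negative fold changes and the list median was -0.46, but 0 passed the threshold over all genes, against 4 lower with the GC offsets and 2 with counts thinned to one total. Adjusted over the list alone, 1 was higher and 4 were lower. Those 4 were Ccr1, with a log2 fold change of -2.68 ± 0.54 (SE), Cxcr6 with -1.56 ± 0.32, Xcr1 with -1.57 and Ccr2 with -1.89, and the higher one was the lymph node homing receptor Ccr7 with 0.58. Ccr2 and Ccr7 were chosen for naming after their values were seen. Xcr1 is also a marker of dendritic cells, and the list of myeloid and dendritic cell markers that holds it had a median of -0.90. Cxcr6 stood at 302 ± 130 CPM in HDAC1-cKO and 892 ± 132 CPM in WT (SD, n = 3; edgeR adjusted p = 0.0526). Ccr4 and Ccr6, receptors that guide effector T cells into inflamed tissue, differed by -0.35 ± 0.25 and -0.16 ± 0.41 on the log2 scale (SE, edgeR adjusted p = 0.537 and 0.897). Without HDAC1-cKO replicate 2 these differences were -0.156 and -0.826 (edgeR adjusted p = 0.759 and 0.120). The difference of Ccr4 was -0.633 without HDAC1-cKO replicate 1, and that of Ccr6 turned to 0.054 to 0.118 without HDAC1-cKO replicate 1 or 3 or WT replicate 2. Of 23 integrins and integrin adaptors, 19 had negative fold changes, the median was -0.43, and 0 passed over all genes, while 1 was higher and 4 were lower adjusted over the list alone. With the GC offsets 2 integrin genes fell, and with counts thinned to one total 1 rose. Itgb2, the beta chain of LFA-1, differed by -0.44 ± 0.10 and Itga5 by 2.37 ± 0.49 (SE, edgeR adjusted p = 0.0683 and 0.0546), and Itga4 by -0.13 ± 0.50 (edgeR adjusted p = 0.934). Itga4 stood at 9.23 CPM in HDAC1-cKO replicate 2 and at 20.7 to 40.5 CPM in the other libraries. Its difference was 0.295 without that library (edgeR adjusted p = 0.616), 0 and 0.004 without WT replicates 2 and 3, and -0.412 to -0.379 without any 1 of the other 3 libraries. Among 14 genes of selectin ligands, Fut7, the fucosyltransferase that makes them, fell by 0.60 ± 0.11 on the log2 scale (SE, edgeR adjusted p = 0.0334), and adjusted over the list alone 1 was higher and 3 were lower; Spn differed by -0.63 ± 0.13 (edgeR adjusted p = 0.0507). By camera with a preset correlation of 0.01 the chemokine receptors and the integrins were shifted lower relative to other genes (adjusted p = 0.00242 and 0.0128 over 32 lists) and the selectin ligand genes were not past the threshold (adjusted p = 0.0801). With an estimated correlation the 3 adjusted p values were 0.427, 0.427 and 0.865. Without HDAC1-cKO replicate 2 the chemokine receptors Cxcr6, Ccr2 and Xcr1, 4 integrin genes and 2 selectin ligand genes fell and Itga5 rose. Without any other library the Fut7 call ended (edgeR adjusted p up to 0.148). The chemokine receptor median was -0.826 without HDAC1-cKO replicate 2 and -0.715 without WT replicate 3. The selectin ligand list was past the camera threshold without HDAC1-cKO replicate 1, on FPKM and with the 10 CPM filter (adjusted p = 0.0241, 0.0175 and 0.0232). Its median of -0.289 was -0.171 without HDAC1-cKO replicate 2 (camera adjusted p = 0.683).

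Genes that define T cells and their activation also leaned lower. Among 21 T cell identity genes, 18 had negative fold changes, with a median of -0.23; Cd3e and Cd2 fell, the latter from 878 ± 43.5 to 559 ± 55.4 CPM (SD, n = 3), and 6 were lower adjusted over the list alone. Of 25 T cell activation genes 0 passed over all genes and 2 were lower adjusted over the list alone, namely the costimulatory receptors Tnfrsf9, with a log2 fold change of -1.35 ± 0.29, and Tnfrsf4, with -0.87 ± 0.20 (SE, edgeR adjusted p = 0.0595 and 0.0718). Camera placed both lists lower (adjusted p = 0.000323 for identity and 0.0209 for activation). With an estimated correlation their adjusted p values were 0.730 and 0.427. The activation list was no longer past the threshold without WT replicate 1 (camera adjusted p = 0.113), and its median of -0.198 was -0.311 and -0.310 without HDAC1-cKO replicate 3 and WT replicate 2. Among 22 naive and quiescence genes Dapl1 rose by 2.64 ± 0.36 and Lef1 fell by 0.63 ± 0.11 on the log2 scale (SE), and adjusted over the list alone 1 was higher and 3 were lower. The median of this list was -0.12 and its mean 0.07, so they differed in sign, and camera gave an adjusted p of 0.487. Without 1 library the median ran from -0.268 to 0.066, the latter without WT replicate 2. In the immediate early and heat shock list, the phosphatase gene Dusp2 fell by 0.95 ± 0.17 on the log2 scale and was also the 1 member lower adjusted over the list alone, while Klf6 differed by -0.54 ± 0.18 (SE). In this list 19 of 20 tested members did not pass, the median was 0.05, the mean -0.06 and the camera adjusted p 0.807, with medians of -0.042 and -0.038 without WT replicates 2 and 3 and 0.211 without WT replicate 1. Without HDAC1-cKO replicate 2, 10 identity genes, 2 activation genes and 3 each of the naive and the immediate early list fell, and the identity median was -0.401. The Cd2, Dapl1, Lef1 and Dusp2 calls ended without any 1 of the other 5 libraries, with edgeR adjusted p up to 0.137, 0.101, 0.144 and 0.153. That of Cd3e without HDAC1-cKO replicate 1 or 3 or WT replicate 3, with edgeR adjusted p up to 0.0716.

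Th1 genes leaned lower in HDAC1-cKO. Of 16 tested Th1 genes 14 had negative fold changes, with a median of -0.62. This was the lowest among the lists of helper cell programmes with all libraries, although the Tfh median was lower without HDAC1-cKO replicate 2 (-0.616 against -0.472) and with limma-voom, and the Th2 median without WT replicate 2 or 3. Il18rap, a chain of the IL-18 receptor, fell from 115 ± 19.4 to 41.0 ± 16.0 CPM, and Id2, a transcriptional regulator of effector cells, from 938 ± 89.1 to 446 ± 83.4 CPM (SD, n = 3); 5 were lower adjusted over the list alone. Camera shifted the Th1 list lower (adjusted p = 0.000395), with an adjusted p of 0.427 with an estimated correlation. Without any 1 library other than HDAC1-cKO replicate 2 the Id2 and Il18rap calls ended (edgeR adjusted p up to 0.104 and 0.159). Without that library 3 Th1 genes fell and Ly6c2, chosen after its values were seen, rose. Among 17 Tfh genes the inhibitory receptor Btla fell by 1.10 ± 0.17 on the log2 scale (SE, edgeR adjusted p = 0.0275), while Slamf6 differed by -0.79 ± 0.20, and 2 were lower adjusted over the list alone (median -0.29, camera adjusted p = 0.0775). This list was past the camera threshold without HDAC1-cKO replicate 2, with a median of -0.616 and 4 genes lower, and without WT replicate 1 (adjusted p = 6.91e-05 and 0.0453). Its median was 0.153 without HDAC1-cKO replicate 1. These fits used the preset correlation of 0.01. With all libraries and an estimated correlation of 0.416 between members, the Tfh camera adjusted p was 0.89. Btla was not called when offsets removed each library's GC trend, a setting chosen after seeing the data, or without any library other than HDAC1-cKO replicate 2 (edgeR adjusted p up to 0.121). The Th2 list (10 tested, 0 passing and 1 lower adjusted over the list alone), the Th17 list (18 tested, 0 passing and, adjusted over the list alone, 1 higher and 2 lower) and the Treg list (15 tested, 0 passing by either adjustment) had medians of -0.49, -0.24 and -0.43 and camera adjusted p values of 0.104, 0.0801 and 0.0775. The Th2 median was -0.293 to -0.269 without HDAC1-cKO replicate 1 or 3 or WT replicate 1. The Treg list was past the threshold without HDAC1-cKO replicate 2 and on FPKM (camera adjusted p = 0.042 and 0.0313). Csf2, the gene of GM-CSF and a member of both the Th17 and the Th1 list, stood at 14.2, 0.999 and 3.53 CPM in the WT libraries and at 0.0307, 0.321 and 0.0980 CPM in the HDAC1-cKO libraries (log2 fold change -5.26 ± 1.14, SE, edgeR adjusted p = 0.0609). The other lowest-p members of these 3 lists were Gata3, with a log2 fold change of -0.62 ± 0.16, Il1rl1 with -1.23 ± 0.47, Ahr with -1.09 ± 0.24, Tnfrsf18 with -0.51 ± 0.18 and Capg with -0.29 ± 0.12 (SE), the last at -0.188 without HDAC1-cKO replicate 3. Gata3 and Tnfrsf18 fell without HDAC1-cKO replicate 2, with log2 fold changes of -0.822 and -0.717 (edgeR adjusted p = 0.00901 and 0.0386), as the 1 Th2 and the 1 Treg gene past the threshold. In the cytotoxic and CD8 lineage list 0 of 21 genes passed by either adjustment (median -0.43, from -0.7 without HDAC1-cKO replicate 1 to 0.304 without WT replicate 1; camera adjusted p = 0.385), with Fasl at -2.44 ± 0.57, or -1.474 without WT replicate 1, and Cd8b1 at 0.46 ± 0.14 (SE).

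**Figure D3:**
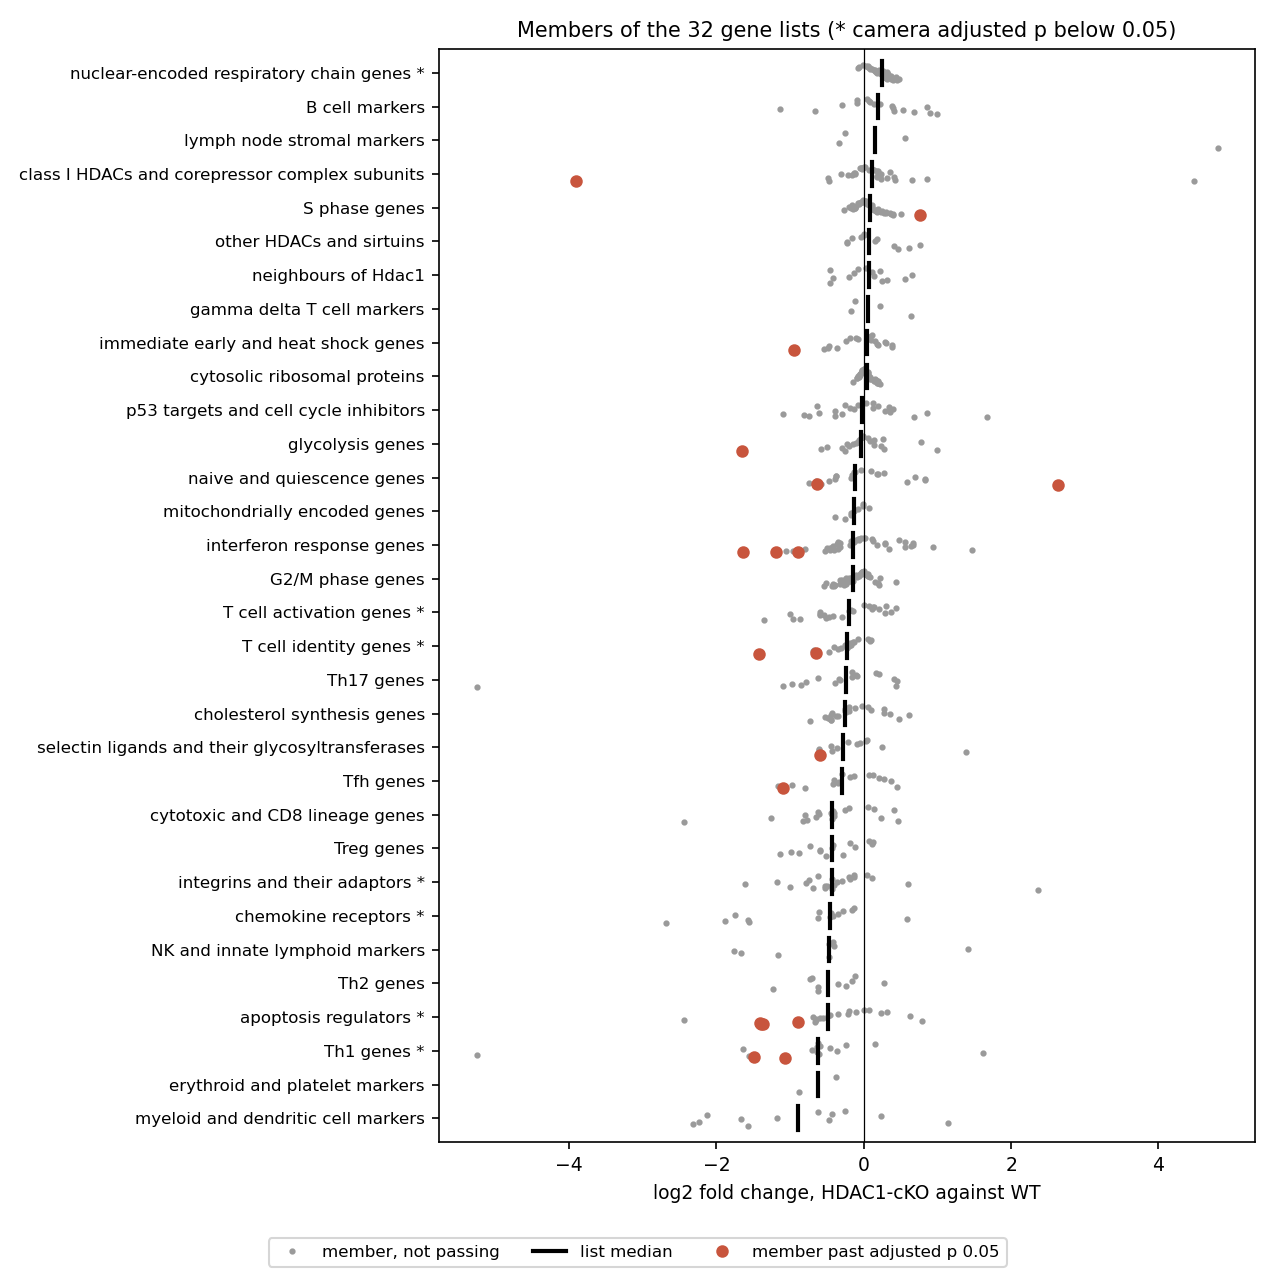
Log2 fold change of HDAC1-cKO against WT for every tested member of the 32 gene lists (grey points, and red points for members past an adjusted p of 0.05 over all genes), with a bar at each list's median; stars mark the 7 lists past the camera threshold with a preset correlation. The lists are ordered by median, from -0.90 for myeloid and dendritic cell markers to 0.24 for the respiratory chain. With an estimated correlation 0 of the 32 lists passed (lowest camera adjusted p = 0.219).

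Apoptosis regulators held 4 genes that fell and 0 that rose among 23 tested. Beside Bcl2a1a, Bcl2a1b and Bcl2a1d, the inflammatory caspase gene Casp4 fell from 48.3 ± 4.85 to 26.1 ± 1.97 CPM (SD, n = 3; log2 fold change -0.89 ± 0.14, SE, edgeR adjusted p = 0.0275), and adjusted over the list alone 1 was higher and 11 were lower. The members that fell thus included both survival factors and a caspase. The list median was -0.49 and camera shifted the list lower (adjusted p = 5.57e-05), with an adjusted p of 0.219 with an estimated correlation. It was the 1 list in which fry, which tests whether genes of a list move one way on balance, passed (adjusted p = 0.0022). Bcl2a1a, Bcl2a1b and Bcl2a1d are near-identical copies that may share reads, so they may not be independent members in these counts and tests. The Casp4 call ended with the GC offsets, and both it and that of Bcl2a1a ended without any library other than HDAC1-cKO replicate 2, with edgeR adjusted p up to 0.120 and 0.0716, while Bcl2a1b lost its call without HDAC1-cKO replicate 1 or 3 (edgeR adjusted p up to 0.0674). Without HDAC1-cKO replicate 2, 6 of the 23 fell. Among 25 p53 targets and cell cycle inhibitors 0 passed over all genes, and adjusted over the list alone 2 were higher and 1 was lower (median -0.03, from -0.105 without WT replicate 1 to 0.062 without WT replicate 3; camera adjusted p = 0.913); Bax differed by 0.69 ± 0.14 and Phlda3 by 1.67 ± 0.40 (SE). Bax rose and Btg2, chosen after its values were seen, fell without HDAC1-cKO replicate 2 (edgeR adjusted p = 0.0228 and 0.0319).

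A few interferon response genes fell. Of 44 tested, Gbp2, Gbp4 and Ifi47 fell, by 1.64 ± 0.28, 1.19 ± 0.16 and 0.89 ± 0.17 on the log2 scale (SE). The level of Gbp2 went from 137 ± 47.9 to 43.8 ± 10.5 CPM (SD, n = 3). These are interferon-gamma inducible GTPases, and as members of multigene families they may share reads with copies. Adjusted over the list alone 7 were lower, the list median was -0.14 and camera gave an adjusted p of 0.0531. With an estimated correlation of 0.396 between members, the camera adjusted p was 0.89. Results of this list in other settings used the preset correlation of 0.01. The list was past the camera threshold without HDAC1-cKO replicate 2, where the median was -0.402 with 6 genes lower and 1 higher, and without WT replicate 1 (adjusted p = 0.000902 and 0.00246). It also passed on FPKM, with the GC offsets and with the 10 CPM filter (adjusted p from 0.0141 to 0.0434). The median was 0.051 without WT replicate 3, and -0.072 and -0.054 without HDAC1-cKO replicates 1 and 3. Ifi47 was not called with upper-quartile factors or GC offsets. The Gbp2 and Ifi47 calls ended without any 1 library other than HDAC1-cKO replicate 2 (edgeR adjusted p up to 0.132 and 0.169), and that of Gbp4 without HDAC1-cKO replicate 1 or 3 or WT replicate 2 or 3 (up to 0.109 in edgeR).

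Cell cycle and metabolic lists held few single genes past the threshold. Gins2, a subunit of the replicative helicase, rose from 77.5 ± 9.88 to 131 ± 4.74 CPM (SD, n = 3; edgeR adjusted p = 0.0311) as the 1 of 45 S phase genes past the threshold by either adjustment, while Rfc2 differed by 0.40 ± 0.09 (SE). The exons of Gse1 on the other strand cover 67.3% of those of Gins2. Gse1 stood at 3.17 CPM in HDAC1-cKO and 3.29 CPM in WT. Of 53 G2/M phase genes 40 had negative fold changes and 0 passed by either adjustment, with Hmgb2 at -0.43 ± 0.10 and Cks2 at -0.40 ± 0.13 (SE). The medians of the S and G2/M lists were 0.09 and -0.15 and their camera adjusted p values 0.0979 and 0.0531. With estimated correlations of 0.659 and 0.56 between members, their camera adjusted p values were 0.892 and 0.89. Results of these 2 lists in other settings used the preset correlation of 0.01, far under these estimates. Without HDAC1-cKO replicate 2 the S phase list was past the threshold with a median of 0.2 and 4 genes higher (camera adjusted p = 4.97e-05), and the G2/M median was -0.02 (camera adjusted p = 0.907), with Hmgb2 as the 1 gene that fell (edgeR adjusted p = 0.0391). Without HDAC1-cKO replicate 1 the S phase median was -0.041, and the G2/M list was past the threshold with a median of -0.28 (camera adjusted p = 0.00119). Without WT replicate 1 both were past it (0.0445 and 0.0327), as the G2/M list was without HDAC1-cKO replicate 3 (0.0289) and the S phase list with the GC offsets (0.0266). The G2/M list also passed on FPKM, without the low-count filter, with the 10 CPM filter and with counts thinned to one total (camera adjusted p = 0.0331, 0.029, 0.0455 and 0.0495). Nuclear-encoded respiratory chain genes had positive fold changes in 34 of 37 cases, with a median of 0.244, or 0.162 without HDAC1-cKO replicate 2, and 0 passed by either adjustment. Ndufv1 stood at 230.5 ± 10.7 CPM in HDAC1-cKO and 176 ± 4.10 CPM in WT (SD, n = 3; edgeR adjusted p = 0.0803), and Ndufa5 differed by 0.46 ± 0.11 (SE) and rose without HDAC1-cKO replicate 2 (edgeR adjusted p = 0.0474). Camera shifted this list higher (adjusted p = 5.57e-05), with an adjusted p of 0.481 with an estimated correlation. The 9 tested mitochondrially encoded genes had a median of -0.14, which turned to 0.149 without HDAC1-cKO replicate 2 and to 0.072 with the GC offsets. Of them 0 passed by either adjustment (camera adjusted p = 0.359). The genes mt-Co1 and mt-Nd6 differed by -0.25 ± 0.20 and -0.39 ± 0.38 (SE), with mt-Co1 at 1038 CPM and mt-Nd6 at 52.6 CPM in HDAC1-cKO replicate 2 and at 1618 to 1922 and 147 to 189 CPM in the other libraries. Without that library the differences were -0.045 and -0.023, and without HDAC1-cKO replicate 3 they were -0.42 and -0.659, with a list median of -0.346. Among 23 tested glycolysis entries the glucose transporter gene Slc2a3 fell from 35.3 ± 7.64 to 11.3 ± 3.95 CPM (SD, n = 3; edgeR adjusted p = 0.0334), also the 1 lower adjusted over the list alone, and Eno1 differed by -0.25 ± 0.09 (SE). The glycolysis median was -0.04 (camera adjusted p = 0.463) and ran from -0.119 without WT replicate 2 to -0.001 without WT replicate 1. Of 24 cholesterol synthesis genes 0 passed over all genes, while 1 was higher and 5 were lower adjusted over the list alone (median -0.25, camera adjusted p = 0.0775), with Idi1 at -0.73 ± 0.18 (SE). This list was past the camera threshold without HDAC1-cKO replicate 2, with a median of -0.387 and 1 gene lower, and without WT replicate 1 (adjusted p = 0.00651 and 0.0445). It also passed on FPKM (camera adjusted p = 0.0461). With all libraries and an estimated correlation of 0.21 between members, its camera adjusted p was 0.865. Its median was -0.133 without WT replicate 2 and -0.16 without HDAC1-cKO replicate 1 (camera adjusted p = 0.293 and 0.284). In the list of 38 cytosolic ribosomal proteins 0 passed by either adjustment (median 0.04, or -0.013 and -0.02 without HDAC1-cKO replicate 2 and WT replicate 2 and 0.101 without WT replicate 1; camera adjusted p = 0.463), with Rps18 at 0.22 ± 0.13 (SE), or 0.076 without HDAC1-cKO replicate 2. Without any 1 library other than HDAC1-cKO replicate 2 the Gins2 and Slc2a3 calls ended (edgeR adjusted p up to 0.132 and 0.136).

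Relatives and neighbours of Hdac1 did not pass the threshold in edgeR with all libraries at full depth. Among 33 class I deacetylase and corepressor complex genes Hdac1 alone was past it over all genes, and adjusted over the list alone 1 was higher and 2 were lower (median 0.11, camera adjusted p = 0.487). The higher one was Rcor2, at 1.40 ± 0.135 CPM in HDAC1-cKO and 0.0572 ± 0.0775 CPM in WT (SD, n = 3; log2 fold change 4.48 ± 0.97, SE, edgeR adjusted p = 0.0605). Of 12 other deacetylases and sirtuins 0 passed and 1 was higher adjusted over the list alone, Sirt2 at 0.46 ± 0.10 (SE), with Sirt3 at 0.62 ± 0.18 (list median 0.08, camera adjusted p = 0.219). In the list of 14 genes around Hdac1 on chromosome 4, 0 passed by either adjustment (median 0.07, camera adjusted p = 0.825), with Iqcc at -0.46 ± 0.17 and Eif3i at 0.25 ± 0.10 (SE). The medians of these 3 lists lay near 0 and turned to -0.023, -0.008 and -0.031 without WT replicate 1, WT replicate 1 and HDAC1-cKO replicate 2. Sirt2 rose and the neighbour Lck, a T cell kinase chosen after its values were seen and also in the identity list, fell without HDAC1-cKO replicate 2 (edgeR adjusted p = 0.0412 and 0.0484), and Rcor2 and Sirt2 rose with counts thinned to one total.

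Markers of other lymph node cells did not pass over all genes in edgeR with all libraries, full depth and no offsets. Their levels ran from under 1 CPM to 372 and 515 CPM in HDAC1-cKO and WT for Il2rb, which activated T cells also express. The B cell list had 18 tested genes and a median of 0.19 (camera adjusted p = 0.143), with Cd79b at 21.1 ± 4.15 CPM in HDAC1-cKO and 10.5 ± 1.87 CPM in WT (SD, n = 3) as the 1 gene higher adjusted over the list alone, and Ighm, at 165 and 88.6 CPM, differing by 0.90 ± 0.34 (SE), or by 0.576 without HDAC1-cKO replicate 2. This list was past the camera threshold with the preset correlation without HDAC1-cKO replicate 1 or WT replicate 2 (adjusted p = 0.0241 and 0.00981). With all libraries and an estimated correlation of 0.626 between members, its camera adjusted p was 0.89. Its median was -0.394 without HDAC1-cKO replicate 2 and -0.268 without WT replicate 1, and Cd79b rose with the GC offsets and with counts thinned to one total. The myeloid and dendritic cell list (12 tested, median -0.90, camera adjusted p = 0.0531) and the NK and innate lymphoid list (8 tested, median -0.47, camera adjusted p = 0.181) each had 1 gene lower adjusted over the list alone, Xcr1 and Il2rb. Xcr1 differed by -1.57 ± 0.39, Lyz1 by -2.32 ± 0.72, Il2rb by -0.47 ± 0.12 and Klrb1c by -1.16 ± 0.53 (SE). Xcr1 and Klrb1c fell without HDAC1-cKO replicate 2, with log2 fold changes of -1.202 and -2.069 (edgeR adjusted p = 0.0279 and 0.0355), and Xcr1 also fell with the GC offsets. The NK median ran from -0.932 to -0.185 without 1 library. The myeloid list was past the camera threshold without WT replicate 1 or HDAC1-cKO replicate 3, with upper-quartile factors and with the GC offsets (adjusted p = 0.0136, 0.0456, 0.0378 and 0.0434). Its median was -0.106 with the 10 CPM filter (adjusted p = 0.871) and -1.685 without HDAC1-cKO replicate 1. The gamma delta T cell list had 4 tested genes (median 0.05, or -0.121 without HDAC1-cKO replicate 2 and 0.339 without HDAC1-cKO replicate 1; camera adjusted p = 0.825), the stromal list 4 (median 0.15, or -0.091 without HDAC1-cKO replicate 1 and 0.879 without WT replicate 1, and mean 1.19; camera adjusted p = 0.463) and the erythroid and platelet list 2 (median -0.63, or -1.001 to -0.261 without 1 library; camera adjusted p = 0.458). Their lowest-p genes were Cd163l1 at 0.65 ± 0.39, or -0.01 without HDAC1-cKO replicate 2, Trdc at -0.18 ± 0.21, or 0.007 without WT replicate 1, Pecam1 at -0.33 ± 0.20, Hba-a1 at -0.88 ± 0.62 and Hba-a2 at -0.37 ± 0.69 (SE). Without 1 library Trdc ran down to -0.35, Pecam1 from -0.519 to -0.221, Hba-a1 from -1.356 to -0.44 and Hba-a2 from -0.673 to -0.049. The other stromal gene was Pdgfrb, which was higher adjusted over the stromal list alone at 1.23 ± 0.854 CPM in HDAC1-cKO and 0.0390 ± 0.0676 CPM in WT (SD, n = 3, edgeR adjusted p = 0.0948). Its log2 fold change of 4.805 was 8.49 without WT replicate 1. The remaining WT libraries held 0 counts of Pdgfrb, so 8.49 is not a measured fold. Of the 25 lists not past the camera threshold, 15 changed the sign of their median and 9 were past it without 1 library. The 7 lists past the camera threshold with a preset correlation all lost it with an estimated one, where the lowest adjusted p among 32 lists was 0.219. Other groupings of the same libraries into 3 and 3 gave 3 to 12 lists with the preset one.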

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

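In all settings where they were tested, the 306 genes called kept the sign of their change. This carries little weight, since the libraries of all 306 separate by genotype and leaving out 1 library could hardly turn a sign. The Hdac1 log2 fold change stayed between -3.99 and -3.76 in all settings. The counts of genes higher in HDAC1-cKO and of genes lower in HDAC1-cKO moved more, from 152 and 154 to 704 and 664 with DESeq2, 747 and 802 with limma-voom and sample weights, 254 and 249 with limma on log2(FPKM + 1), and 405 and 413 at an adjusted p under 0.1. The lower genes numbered 243 without the low-count filter and 86 with a 2-fold minimum. With the GC offsets, added after seeing the data, 241 were higher and 247 lower, and 236 were lower with GC and length offsets. Leaving out 1 library gave 15 to 258 higher and 10 to 368 lower genes, and the highest values came without HDAC1-cKO replicate 2. That fit also lost 1 library yet gave more calls. The lower counts without each other library thus cannot be put down to sample number alone. The causes of these and the other shifts were not tested. The gene lists past the threshold numbered 7, with 12 on FPKM, 12 with GC offsets, 7 to 12 without 1 library, 0 with an estimated correlation (camera) and 1 with fry. Same-numbered libraries of the genotypes did not deviate together (correlations 0.024, -0.002 and -0.042). With so few libraries this cannot exclude a shared day or batch. The column names of same-numbered libraries carry consecutive numbers, so pairing stays possible. A replicate block gave 34 higher and 31 lower genes. The block ended the calls of Gbp4, Btla, Casp4, Gins2, Cd2, Lef1, Fut7, Dusp2, Il18rap and Ifi47. It put the Tfh, B cell and myeloid lists past the camera threshold with the preset correlation (adjusted p = 0.0351, 0.0233 and 0.0025). Of 1577 values of named genes under other settings, 1339 stayed on their side of the threshold, 103 lost and 135 gained the call. Of 570 list results by camera with the preset correlation 530 stayed, 1 lost and 39 gained it. These 570 leave out the estimated correlation and fry. At this depth and n, edgeR recovered 39.2% of simulated 2-fold changes among 15519 genes, so a gene not called is not shown to be unchanged.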

Other observations

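Of the 152 genes that rose, 29 had a WT mean under 1 CPM. They were singled out after their values were seen. Beside Gcg and G0s2 they included Urah, from 0.466 ± 0.407 to 16.0 ± 7.71 CPM, Itgb5, an integrin chain, from 0.782 ± 0.421 to 6.40 ± 1.29 CPM, Ncs1, a neuronal calcium sensor, from 0.476 ± 0.291 to 5.36 ± 0.715 CPM, and Plxnb2, a semaphorin receptor, from 0.853 ± 0.602 to 5.57 ± 0.744 CPM (SD, n = 3). Syngr1, a synaptic vesicle protein, rose from 0.818 ± 0.360 to 6.24 ± 0.526 CPM and Cryab, a small heat shock protein, from 0.722 ± 0.243 to 4.35 ± 1.76 CPM (SD, n = 3).

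The tests of shared reads, of markers of other cells and of the 29 genes at equal depth were chosen only after the result was seen. Genes near silence in WT were more common among the higher genes than genes near silence in HDAC1-cKO were among the lower ones, at 19.1% (29 of 152) against 5.8% (9 of 154), with an exact Fisher p of 0.000457 (two-sided), although genes are not independent replicates. B cells are argued against, since the 9 of 18 tested B cell markers at a mean of at least 10 CPM had a median log2 fold change of 0.39 (95% bootstrap interval 0.07 to 0.9), against a lower quartile of 2.68 for the 29 genes. The most abundant, Ighm and Cd74, stood at 165 and 156 CPM in HDAC1-cKO and 88.6 and 119 CPM in WT, and without 1 library the median of all 18 markers ran from -0.394 to 0.685. The B cell interval resamples markers that move together (estimated correlation 0.626 in the list), so it does not measure the spread between libraries. The 29 genes were picked for a rise from a low level, which favours large folds. The other 5 cell types stay open, although the sort for donor-derived 2D2+ CD4+ cells selects against them, since at most 2 tested markers of each reached that level. The stromal marker Pdgfrb had a log2 fold change of 4.8, without passing over all genes (edgeR adjusted p = 0.0948). With all libraries thinned to 19956153 counts the excess was 8.9 percentage points (95% interval 3.3 to 15.1) against 13.2 at full depth, and 21 of the 29 genes were called higher again, 7 having fallen under the expression filter; so the deeper WT libraries remain possible for part of the excess. A hypothesis that stays open is that HDAC1 keeps genes near silence in these T cells, and whether they are direct targets was not tested.

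Higher genes were richer in GC than lower genes, with median transcript GC of 54.5% against 46.7%, a gap of 7.8 percentage points (95% bootstrap interval 6.56 to 9.44). Depth is argued against, since the gap was 8.5 points with all libraries thinned to one total (7.28 to 9.84). Without HDAC1-cKO replicate 2, the library with the GC trend, the gap was 3.98 points (2.37 to 5.41), with GC offsets it was 3.89 (2.48 to 5.17), and with GC and length offsets 3.14 (1.31 to 4.32). The trend of that library is thus argued against as the whole source. The bound set beforehand for a gap that mostly rests on this library was 3.9 points, and the 3.98 points without it lay just above. Whether the trend accounts for most of the gap stays open, because all 3 intervals lie on both sides of that bound. Placing the whole interval against the bound was not part of the rule set beforehand. The intervals resample genes, so they do not measure the spread between libraries. An effect of the genotype on GC-rich genes stays possible and was not tested.

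Processed pseudogenes fell with Hdac1. Gm10093, Gm4864 and AC125456.1, the first 2 chosen after their values were seen, had log2 fold changes of -3.93 ± 0.14, -3.99 ± 0.20 and -3.77 ± 0.22 (SE), against -3.91 ± 0.12 for Hdac1, and share 80.4%, 11% and 12.2% of their 50-base stretches with Hdac1 transcripts. Reads of Hdac1 counted at these copies are a candidate explanation. Of the 4 tested genes that share at least 5% of their stretches, 75% fell, the exception being Zfp131, which shares 5.7% (log2 fold change -0.19 ± 0.23, SE); 4 genes are too few to settle it.

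The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share of splits under 0.05. The real split gave 152 genes higher and 154 lower, as the 1 split of 10 with results as large, and the highest other split gave 0 in edgeR, with 196 to 1426 genes at an unadjusted p under 0.05 against 2640. Each other split mixes both genotypes in each group, so any genotype difference adds to its spread within groups and can lower its calls. The 0 is therefore no measure of chance alone. Of lists past the camera threshold with a preset correlation the real split gave 7 and the highest other 12, and 8 of the 10 splits gave at least as many.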
